A study of Rattus norvegicus with 60 samples.

How the data were processed

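Total RNA of mesenteric adipose tissue and liver was sequenced after depletion of ribosomal RNA (TruSeq Stranded Total RNA with Ribo-Zero) on a NovaSeq instrument in paired reads of 150 nt, with a target of 50 M (mega) read pairs per library, per the labels. Per the submitters' processing notes, the authors used Trimmomatic, HISAT2, HTSeq and DESeq2 with the rat assembly rn7; no versions or settings are stated. The deposited files hold, for each of the 60 libraries, a raw read count per gene as made by the authors with HTSeq. For 6 comparisons the authors also deposited DESeq2 tables with a log2 fold change and an adjusted p-value per gene. Those authors' values are quoted only where the text names the authors' deposited table. The 90 per-sample columns of normalised counts that accompany these tables were not used, since the raw counts of the same libraries are present.

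The count files list 34322 genes by symbol, without another identifier. Of these, 27234 match a current symbol of the reference gene table and 28874 match a symbol or a synonym, 4808 had no count in any library, and 8 entries are nuclear rRNA genes. Gene positions are not given, because the reference table belongs to another assembly (GRCr8) than the one the authors mapped to. Samples were placed in groups by tissue, prenatal exposure, stroke status and sex as the labels state. Pairs of libraries of the same group were checked for duplicated data over genes with at least 20 counts; the variance ratio (chi-square per degree of freedom) of the 84 pairs lay between 11.1 and 165, where copies would give a value near 0.

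Each tissue was fitted on its own with edgeR 4.0.16 in R 4.3.3: TMM scaling, filterByExpr by the 8 groups (minimum count 10), and a robust quasi-likelihood fit with a mean for each exposure, stroke and sex group. Contrasts averaged the sexes equally and were tested two-sided, with Benjamini-Hochberg adjustment over 18546 adipose or 15889 liver genes and a call at an adjusted p under 0.05. The comparisons were stroke against naive within each exposure, PAE against control within naive and within stroke animals, their interaction, male against female, and the difference between the sexes in the response to stroke and to PAE. Fold changes are printed as log2 with the standard error of the fit, or as fold. CPM are counts per M counts of the TMM-scaled library size, as mean ± SD over libraries. List levels are means of log2 CPM with a prior count of 2; their differences within each sex were computed after the lists had been tested, are printed where the sexes disagreed, and were not tested between the sexes. A count of 3 in a library is taken as the floor of detection; no fold is printed for a gene at or under it in both groups. The floor covers counting error only. The median SE of log2 changes was 0.125 to 0.135 in adipose tissue and 0.155 to 0.169 in liver, and 0.184 and 0.229 for the interaction, over genes with a mean log2 CPM of at least 1.

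Lists of pathway genes and cell type markers, 44 in all, and the rule for named genes were fixed before the data were examined. Lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01, adjusted over the lists of a tissue within a comparison, and again with the correlation estimated from the data. Beside the count of members called over all genes stands the count adjusted over the list alone. The rule named, for each comparison, the 6 largest increases and the 6 largest decreases among called genes with a mean log2 CPM of at least 1 and the same sign in both sexes. It added up to 4 called members of each pathway list that passed camera, the 5 genes with the smallest p where fewer than 5 passed, and 10 fixed genes per tissue. For sex it named fixed sex-linked genes, and for sex differences in response the 10 genes with the smallest p. Called markers of cell types, called members of lists beyond 4 and genes of the authors' deposited tables were chosen after their values were seen. Named genes that lost their call in many fits or lay near the floor are not all printed, and some genes and 1 list are not reported here. Direction in single libraries was read against the mean of the comparison group of the same sex.

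Shares of rRNA and haemoglobin were compared by permutation tests within sex (two-sided, 100000 resamples, Benjamini-Hochberg over 24 tests). Comparisons of 4 with 4 libraries used the exact permutation test. Counts simulated with the depths and spread of these libraries (18351 adipose and 15725 liver genes) had known changes for stroke in controls only. edgeR called 44%, 78%, 94% and 96% of adipose genes changed 1.5-, 2-, 3- and 4-fold, and 28%, 70%, 98% and 98% of liver genes. Of all calls 8 (4.88%) and 7 (4.55%) were false, and power in other comparisons was not tested.

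Chosen with the design were these alternatives: DESeq2 1.42.0 with its own size factors and the same design, RLE in place of TMM scaling, no filter on low counts, no sex term, a fit on the compared libraries alone, a block for the number in the sample titles, and leaving out each library in turn. Alternatives chosen after seeing the data were the removal of rRNA genes before scaling, the log2 nuclear rRNA share as a covariate, leaving out libraries with over 40% nuclear rRNA, and, for adipose lists, leaving out PAE stroke male 2 and a covariate of the mean adipocyte marker level. Counts of other splits used 100 regroupings of the libraries per comparison, drawn with seed 1. Genes with counts too low for filterByExpr were left out of the tests.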

Results

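RNA was sequenced from mesenteric adipose tissue and liver of 5-month-old Sprague-Dawley rats of both sexes. Their dams had breathed ethanol vapour (prenatal alcohol exposure, PAE) or room air (controls) for 12 days between gestational days 8 and 20. Animals of the stroke groups had undergone middle cerebral artery occlusion, a surgical model of ischaemic stroke, 2 days before dissection, and the others were stroke-naive littermates. The labels describe no sham operation, so each stroke comparison covers the whole procedure. Each tissue gave 30 libraries: 4 females in each of the 4 exposure and stroke groups, 4 males in each PAE group and 3 males in each control group. Raw gene counts summed to 9.81 M (mega) to 25.4 M per adipose library (median 16.4 M) and to 7.72 M to 30.4 M per liver library (median 17.4 M). Between 21050 and 24656 genes had a count in an adipose library, and between 17021 and 20392 in a liver library.

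Nuclear ribosomal RNA (rRNA) took 0.469% to 50.0% of the counts of the adipose libraries (median 15.3%) and 0.626% to 51.1% of the liver libraries (median 3.06%). In adipose tissue its mean share was 26.9% ± 17.1 (SD, n = 4) in PAE naive females and 1.55% ± 0.817 (n = 4) in PAE stroke males. In liver it was 32.6% ± 16.9 (n = 3) in control stroke males and 1.85% ± 0.397 (n = 4) in control stroke females. The 24 permutation tests of rRNA and haemoglobin shares between exposure or stroke groups, averaged over the sexes, all gave an adjusted p of 0.984, though in adipose tissue nuclear rRNA took 0.469% to 2.44% in the 4 PAE stroke males and 12.6% to 17.5% in the 3 control stroke males. Mitochondrial rRNA took 9.87% to 31.5% of the adipose counts and 1.70% to 12.6% of the liver counts. The counts outside rRNA came to 4.74 M to 21.3 M per adipose library and 4.19 M to 28.7 M per liver library.

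**Figure D1:**
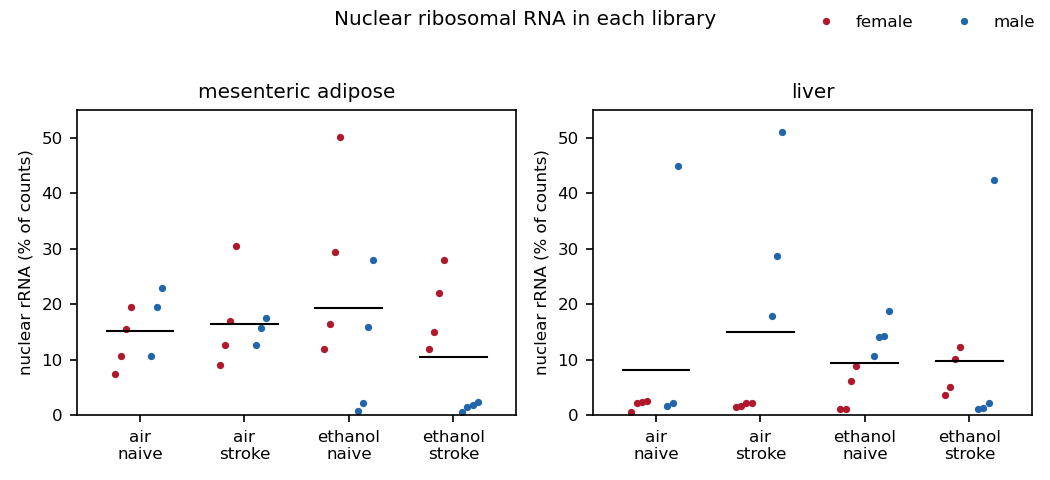
Nuclear rRNA as a percentage of all counts (y axis) in each library of mesenteric adipose tissue (left) and liver (right), by exposure and stroke group (x axis), with red points for females, blue points for males and a line at the group mean. The 4 adipose libraries of PAE stroke males lay between 0.469% and 2.44%.

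The liver comparison of 7 stroke with 7 naive control animals asked what stroke did to the liver of animals exposed to room air. Acute phase genes rose: 14 of 22 measured members were called higher, and 18 passed adjusted over the list alone. Their median log2 change was 1.05 (camera adjusted p = 8.33e-30, and 0.00099 with an estimated correlation). Lcn2, which encodes the iron-sequestering protein lipocalin 2, was 44.3-fold higher (log2 5.47 ± 0.892 SE, edgeR adjusted p = 0.00123), at 87.9 ± 104 CPM (counts per M counts of the library; mean ± SD, n = 7) against 1.91 ± 1.24 (n = 7). Haptoglobin (Hp), which binds free haemoglobin, rose 3.48-fold (log2 1.80 ± 0.191 SE, edgeR adjusted p = 1.85e-06), from 2867 ± 624 to 10109 ± 4086 CPM. The orosomucoid gene Orm1 rose 6.69-fold (log2 2.74 ± 0.34 SE) and the haemopexin gene Hpx rose 2.29-fold (log2 1.20 ± 0.186 SE). The protease inhibitor gene A2m rose by log2 5.01 ± 0.864 SE (adjusted p = 0.00193). All 7 stroke livers lay above the naive mean of their own sex for these 5 genes.

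Complement and coagulation genes also rose in control livers, with 12 of 32 members called higher and 20 adjusted over the list alone (median log2 change 0.39; camera adjusted p = 1.06e-19, and 0.001 with an estimated correlation). Kng1, the kininogen gene, rose 10.6-fold (log2 3.41 ± 0.352 SE, edgeR adjusted p = 1.85e-06), from 368 ± 119 to 3779 ± 3457 CPM, and the complement genes C5 and C8b rose 2.07-fold and 1.48-fold. Cholesterol synthesis genes rose as a list: 9 of 25 were called higher and 20 passed adjusted over the list alone, with a median log2 change of 0.87 (camera adjusted p = 8.84e-23, and 0.0366 with an estimated correlation). Ebp, which encodes a sterol isomerase, rose 2.15-fold and Acat2 rose 3.18-fold. Of 22 fatty acid synthesis genes, 6 were called higher and 14 adjusted over the list alone, with a median log2 change of 0.85 (camera adjusted p = 3.42e-14, and 0.0504 with an estimated correlation). Acly, the enzyme that makes cytosolic acetyl-CoA from citrate, rose 3.10-fold (log2 1.63 ± 0.287 SE, edgeR adjusted p = 0.00154).

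Fatty acid oxidation genes went the other way in control livers: 9 of 30 were called lower and 13 adjusted over the list alone, with a median log2 change of -0.34 (camera adjusted p = 2.1e-13, and 0.0798 with an estimated correlation). The acyl-CoA thioesterase gene Acot2 fell 2.61-fold (log2 -1.39 ± 0.204 SE, edgeR adjusted p = 0.000185), and Ech1 and the omega-hydroxylase gene Cyp4a3 fell 2.26-fold and 1.74-fold. Among 9 measured MHC class II genes 3 fell (RT1-Da by log2 -1.04, RT1-Db1 by -1.11 and Cd74 by -0.94) and 4 passed adjusted over the list alone (camera adjusted p = 0.00111, and 0.233 with an estimated correlation). Ccnd1, which encodes cyclin D1, was 6.33-fold lower (log2 -2.66 ± 0.317 SE, edgeR adjusted p = 1.52e-05), at 11.7 ± 6.75 CPM in stroke against 61.9 ± 23.4 CPM in naive livers. The carboxylesterase gene Ces1d fell 3.30-fold and the mitochondrial carrier gene Slc25a30 fell 3.26-fold. All 7 stroke livers lay below the naive mean of their sex for Acot2, Ccnd1, Ces1d and Slc25a30.

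Other lists passed camera in control livers, none of them with an estimated correlation. Of 22 unfolded protein response genes 4 rose, and 9 adjusted over the list alone (camera adjusted p = 2.17e-05, and 0.167 with an estimated correlation); the 4 were Chac1, Asns, Sdf2l1 and Edem1. Of 29 extracellular matrix genes 4 fell (Col14a1, Bgn, Mmp2 and Col6a3), and adjusted over the list alone 5 were lower and 2 higher (camera adjusted p = 1.5e-05, and 0.262 with an estimated correlation). The female log2 change of Col6a3 was 0.01. Of 27 cell cycle genes 2 fell and 8 adjusted over the list alone (camera adjusted p = 1.03e-06, and 0.148 with an estimated correlation). The 34 interferon response genes had a median log2 change of -0.69, with 15 lower adjusted over the list alone but none over all genes (camera adjusted p = 1.49e-08, and 0.298 with an estimated correlation). Of 61 oxidative phosphorylation genes 1, Ndufa5, rose by log2 0.77 over all genes and adjusted over the list alone, with a list median of 0.33 (camera adjusted p = 2.23e-14, and 0.216 with an estimated correlation). The 51 ribosomal protein genes had a median of 0.24 with no single call (camera adjusted p = 2.39e-06, and 0.507 with an estimated correlation). In heat shock (14 members) and circadian clock (18) lists, camera adjusted p were 0.0216 and 0.00409, and adjusted p = 0.481 and 0.12 with an estimated correlation. The called member of these lists was Hspa8 (log2 -0.65). The glucocorticoid-activating gene Hsd11b1 was also called, with a log2 change of 0.91.

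Marker lists of cell types moved in the same control livers. Of 6 measured neutrophil markers 3 rose, S100a9 by log2 2.47, Csf3r by 1.41 and Mmp8 by 3.06, with 3 adjusted over the list alone (camera adjusted p = 0.00413, and 0.162 with an estimated correlation). Of 12 hepatocyte markers 4 rose over all genes and 4 adjusted over the list alone (camera adjusted p = 1.03e-06, and 0.001 with an estimated correlation). Those 4 were Apoa1, Serpina1, Fgb and Hpx, which encode plasma proteins, while Alb, the albumin gene, had a log2 change of -0.01. The 11 B and plasma cell markers had a median of -0.64, with 1 lower adjusted over the list alone (camera adjusted p = 0.0345, and 0.466 with an estimated correlation). Mean nuclear rRNA was 32.6% in control stroke males and 16.2% ± 24.9 (n = 3) in control naive males.

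Of 15889 liver genes tested with edgeR, 468 were called in control animals (317 higher and 151 lower), and 193 of them changed over 2-fold. Fkbp5, a glucocorticoid-induced gene, and Cyp7a1, the rate-limiting enzyme of bile acid synthesis, had log2 changes of 0.62 and 2.42 and did not pass (adjusted p = 0.408 and 0.0578). Pck1 (-0.33), Igfbp1 (1.98), Fgf21 (-0.28) and Cyp2e1 (-0.70) did not pass either, at adjusted p of 0.458, 0.0528, 0.732 and 0.0706. Among the 47 named genes called here, 30 were called whichever single library was left out, Lcn2, A2m and Hp among them. The number of called genes was 309 without control naive female 3, and 287, 286 and 279 without control naive males 1, 2 and 3. It was 222 with the sexes pooled, which ended the calls of RT1-Da, RT1-Db1, Cd74, Sdf2l1, Edem1, Col14a1, Bgn, Mmp2, Col6a3, Hspa8 and Hsd11b1, and 736 by DESeq2. Leaving out the 3 liver libraries with over 40% nuclear rRNA ended the calls of Chac1, RT1-Da, RT1-Db1, Sdf2l1, Col6a3 and Hspa8.

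The liver comparison of 8 stroke with 8 naive PAE animals asked the same of animals exposed to ethanol before birth. Of 22 acute phase genes 13 rose, and 17 adjusted over the list alone, with a median log2 change of 0.89 (camera adjusted p = 1.93e-23, and 0.00251 with an estimated correlation). Lcn2 was 46.1-fold higher (log2 5.53 ± 0.806 SE, edgeR adjusted p = 0.000165), at 112 ± 58.7 CPM (SD, n = 8) against 2.40 ± 3.35 (n = 8). Hp rose 3.23-fold (log2 1.69 ± 0.176 SE), Orm1 rose 6.33-fold (log2 2.66 ± 0.312 SE) and A2m rose by log2 5.22 ± 0.788 SE. Of 32 complement and coagulation genes 16 rose, and 20 adjusted over the list alone (camera adjusted p = 2.34e-17, and 0.00251 with an estimated correlation). Kng1 rose 9.85-fold (log2 3.30 ± 0.321 SE, edgeR adjusted p = 4.03e-07), and the complement gene Cfb and the coagulation factor genes F7 and F10 rose 1.79-fold, 1.71-fold and 1.43-fold. All 8 stroke livers lay above the naive mean of their sex for each of these 8 genes.

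Cholesterol synthesis genes rose in PAE livers in 22 of 25 members, and in all 25 adjusted over the list alone, with a median log2 change of 1.18 (camera adjusted p = 7.98e-40, and 0.00265 with an estimated correlation). Cyp51, the sterol demethylase gene, rose 2.77-fold (log2 1.47 ± 0.165 SE, edgeR adjusted p = 1.24e-06), from 224 ± 70.7 to 612 ± 108 CPM, and Pmvk and Acat2 rose 2.68-fold and 4.81-fold. Of 22 fatty acid synthesis genes 12 rose, and 15 adjusted over the list alone (median log2 change 1.12; camera adjusted p = 2.71e-13, and 0.0547 with an estimated correlation). Acly rose 3.35-fold, Acss2 3.95-fold and the desaturase gene Fads1 2.82-fold. Among 30 fatty acid oxidation genes 10 fell and 1 rose, and 16 and 1 adjusted over the list alone (median log2 change -0.39; camera adjusted p = 3.44e-09, and 0.16 with an estimated correlation). Acot2 fell 2.08-fold (log2 -1.05 ± 0.186 SE, edgeR adjusted p = 0.000655), Ech1 2.13-fold and Cyp4a3 1.62-fold.

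Lists of glucose production and of hormone and stress responses passed camera in PAE livers, none of them with an estimated correlation and not all in 1 direction. Of 17 gluconeogenesis and insulin genes 5 rose, and 7 adjusted over the list alone (camera adjusted p = 9.68e-07, and 0.148 with an estimated correlation). Ppargc1a, a coactivator of gluconeogenic transcription, rose 6.91-fold (log2 2.79 ± 0.484 SE, edgeR adjusted p = 0.00095), and Igfbp1 and the mitochondrial enzyme gene Pck2 rose 5.78-fold and 2.12-fold. Of 18 glucocorticoid response genes 3 rose and 1 fell, with 3 and 1 adjusted over the list alone (camera adjusted p = 0.00226, and 0.328 with an estimated correlation). Those were Fkbp5 (log2 1.77), Ddit4 (3.15), Tat (1.34) and Angptl4 (-1.05). Of 22 unfolded protein response genes 8 rose, and 11 adjusted over the list alone (camera adjusted p = 4.67e-07, and 0.115 with an estimated correlation), among them Sdf2l1 (3.43-fold) and the chaperone gene Calr (2.13-fold). Of 14 heat shock genes 5 fell, and 6 adjusted over the list alone (camera adjusted p = 2.77e-05, and 0.237 with an estimated correlation), among them Hspa8 (log2 -1.01 ± 0.167 SE) and Hsph1 (-0.82). Of 17 immediate early genes 3 rose and 1 fell, with 7 and 2 adjusted over the list alone (camera adjusted p = 0.0385, and 0.684 with an estimated correlation), Btg2 rising by log2 2.74.

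Oxidative phosphorylation genes rose in 20 of 61 members, and in 40 adjusted over the list alone, with a median log2 change of 0.39 (camera adjusted p = 5.31e-16, and 0.208 with an estimated correlation), among them Ndufb7 by 0.72 and Cox5b by 0.74. Ribosomal protein genes rose in 13 of 51 members, and in 32 adjusted over the list alone, with a median of 0.43 (camera adjusted p = 2.51e-11, and 0.406 with an estimated correlation), among them Rplp1 by 1.48 and Rplp2 by 1.10. Their mean level was 6.53 log2 CPM in PAE stroke female 4, against 4.93 to 5.54 in the other stroke livers, and without it the change of the level went from 0.39 to 0.21. Of 18 circadian clock genes 3 rose and 5 adjusted over the list alone (camera adjusted p = 0.00899, and 0.149 with an estimated correlation), Cry2 by 0.71. Of 27 cell cycle genes 2 fell and 7 adjusted over the list alone (camera adjusted p = 0.00197, and 0.366 with an estimated correlation). Of 6 neutrophil markers 4 rose over all genes and adjusted over the list alone (camera adjusted p = 7.48e-05, and 0.0547 with an estimated correlation), S100a9 by log2 2.56 and Mmp8 by 3.12. Of 12 hepatocyte markers 4 rose (Apoa1, Serpina1, Fgb and Hpx) and 6 adjusted over the list alone (camera adjusted p = 8.47e-06, and 0.00251 with an estimated correlation). Of 10 mesothelium markers 1 rose, Krt8 by 0.43, over all genes and adjusted over the list alone (camera adjusted p = 0.021, and 0.293 with an estimated correlation).

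In PAE livers edgeR called 1112 of 15889 genes (753 higher and 359 lower), 368 of them over 2-fold, and 579 genes with the sexes pooled. Cyp7a1 rose 4.82-fold (log2 2.27 ± 0.626 SE, adjusted p = 0.0292) and Cyp2e1, the ethanol-oxidising cytochrome, fell 1.85-fold (log2 -0.89 ± 0.196 SE, adjusted p = 0.00524); both calls ended with the sexes pooled, as did those of F7 and Angptl4. Osgin1 and Ccnd1 fell 4.46-fold and 4.63-fold, and the protease inhibitor gene Wfdc21 rose 11.7-fold. Pck1 and Fgf21 did not pass, at log2 0.12 and 0.09 (adjusted p = 0.783 and 0.917). Of the 66 named genes called, 55 were called whichever single library was left out. The genes called higher in control and in PAE livers shared 249 members where 15.0 would be shared by chance, and those called lower shared 73 where 3.41 would be; the 2 comparisons have no library in common.

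**Figure D2:**
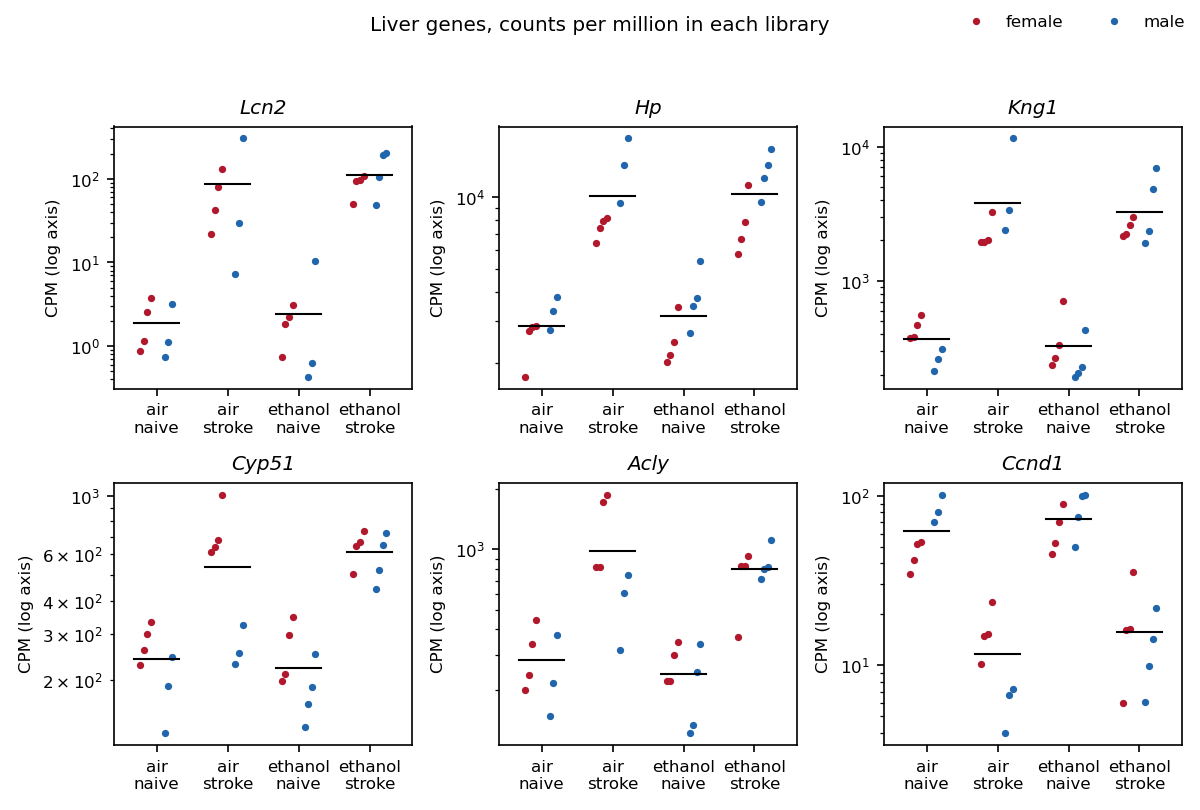
CPM (y axis, log scale) of Lcn2, Hp, Kng1, Cyp51, Acly and Ccnd1 in each liver library by exposure and stroke group (x axis), with red points for females, blue points for males and a line at the group mean. The stroke libraries of both exposures lay above the naive mean of their sex for Lcn2, Hp and Kng1 and below it for Ccnd1.

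Whether the liver's stroke response differed with prenatal exposure was asked by the exposure by stroke interaction. No gene passed in edgeR, 455 genes had an unadjusted p under 0.05 where chance alone would give 794, and DESeq2 called 0. The stroke response of Hp differed between exposures by log2 -0.11 ± 0.252 SE, that of Orm1 by -0.08 ± 0.432, that of Lcn2 by 0.06 ± 1.06 and that of A2m by 0.21, none of which passed. Fkbp5 had a difference of 1.15 ± 0.478 and Pck1 of 0.46, and the 5 genes with the smallest p were Sema3e (1.61 ± 0.434), Pcsk5 (-0.81 ± 0.222), Tbc1d2 (0.71 ± 0.197), Tmtc2 (-0.96 ± 0.269) and Pck2 (0.79 ± 0.222), all at an adjusted p of 1. All 25 cholesterol synthesis genes had a positive difference, with a median of 0.31 (camera adjusted p = 2.21e-05, and 0.624 with an estimated correlation). Of 34 interferon response genes 30 had a positive difference, with a median of 0.42 (camera adjusted p = 4.26e-05, and 0.75 with an estimated correlation). Extracellular matrix genes had a median of 0.32 (camera adjusted p = 2.21e-05, and 0.622 with an estimated correlation), and gluconeogenesis and insulin genes 0.23 (camera adjusted p = 0.000895, and 0.622 with an estimated correlation). Mesothelium markers, macrophage markers and ribosomal protein genes passed camera too, with medians of 0.44, 0.27 and 0.22, at adjusted p = 0.622, 0.75 and 0.804 with an estimated correlation. By sex, cholesterol synthesis levels differed by -0.23 in females and 0.92 in males, and interferon levels by -0.07 and 0.91. Without PAE stroke female 4 the difference of ribosome levels turned from 0.13 to -0.05, and without PAE naive male 2 that of macrophage levels went from 0.29 to 0.11. The median SE of the interaction was 0.229 on the log2 scale. Leaving out the 3 libraries with over 40% nuclear rRNA gave 1 called gene.

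The liver comparison of 8 PAE with 7 control naive animals asked what ethanol before birth left in the adult liver. No gene passed in edgeR, 347 had an unadjusted p under 0.05 where 794 would by chance, and DESeq2 called 0. The smallest p belonged to the transporter genes Slc16a4 (log2 0.84 ± 0.185 SE) and Slc13a4 (0.82 ± 0.202), to Parvb (-0.55 ± 0.125), to the membrane progestin receptor gene Paqr7 (0.63 ± 0.16) and to Gcnt4 (0.63 ± 0.165). All 8 PAE livers lay on the same side of the control mean of their sex for these 5 genes, and edgeR gave each an adjusted p of 1. Log2 differences were 0.12 for Orm1, 0.10 for Hp, 0.24 for Lcn2, 0.76 for A2m, -0.71 for Fkbp5, 0.80 for Cyp7a1, -0.13 for Pck1, -0.05 for Igfbp1, 0.41 for Fgf21 and 0.30 for Cyp2e1, also at an adjusted p of 1. All 15 macrophage markers were lower on average, with a median of -0.31 (camera adjusted p = 3.11e-08, and 0.526 with an estimated correlation). Of 30 fatty acid oxidation genes 27 were higher, with a median of 0.15 (camera adjusted p = 0.000137, and 0.888 with an estimated correlation), and of 34 interferon response genes 28 were lower, with a median of -0.16 (camera adjusted p = 4.29e-06, and 0.897 with an estimated correlation). The median differences of the other lists that passed camera were 0.08 for oxidative phosphorylation, 0.13 for negative acute phase, 0.14 for hepatocyte markers, -0.30 for mesothelium markers and -0.24 for MHC class II. Without PAE naive male 2 the differences of list levels went from -0.39 to -0.20 for macrophage, from -0.37 to -0.17 for interferon and from -0.28 to -0.10 for MHC class II genes. With an estimated correlation the adjusted p = 0.897, 0.228, 0.294, 0.326 and 0.888 for these 5 lists. The authors' deposited table called 5 genes here (Slc16a4, Paqr7, Nrep, Afm and Hao2), at log2 changes of 0.67, 0.54, 0.68, 0.31 and 0.59.

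In stroke animals, 8 PAE livers were compared with 7 control livers to ask whether exposure groups differed after stroke. No gene passed in edgeR, 1030 had an unadjusted p under 0.05 where 794 would by chance, and DESeq2 called 12. The cytochrome gene Cyp3a2 had the smallest p (log2 1.70 ± 0.32 SE, edgeR adjusted p = 0.199), at 1223 ± 1330 CPM in 8 PAE livers and 557 ± 787 CPM in 7 control livers, and all 8 PAE livers lay above the control mean of their sex. Paqr7 (0.75 ± 0.161), Igfals (0.66 ± 0.144), Ankh (0.66 ± 0.147) and RGD1566189 (1.06 ± 0.245) followed at an adjusted p of 0.414. The acute phase genes Hp, Orm1, Lcn2 and A2m differed by log2 -0.01, 0.04, 0.30 and 0.97, and Fkbp5, Cyp7a1, Pck1, Igfbp1, Fgf21 and Cyp2e1 by 0.44, 0.65, 0.33, 0.50, 0.78 and 0.11, none of which passed. All 25 cholesterol synthesis genes were higher on average, with a median of 0.27 (camera adjusted p = 4.11e-05, and 0.524 with an estimated correlation), and fatty acid oxidation genes had a median of 0.21 (camera adjusted p = 5.09e-06, and 0.498 with an estimated correlation). The other lists that passed camera had medians of 0.27 (extracellular matrix), 0.26 (gluconeogenesis and insulin, 1 member higher adjusted over the list alone), 0.16 (oxidative phosphorylation), 0.66 (erythroid markers), 0.24 (ribosome), 0.13 (negative acute phase, 2 members adjusted over the list alone), 0.18 (bile acid metabolism), 0.26 (unfolded protein response) and 0.33 (cell cycle). With an estimated correlation their adjusted p = 0.511, 0.498, 0.769, 0.511, 0.927, 0.498, 0.498, 0.658 and 0.724. In females and in males cholesterol synthesis levels differed by -0.41 and 0.95, extracellular matrix levels by -0.14 and 0.53 and bile acid levels by -0.01 and 0.50. Without PAE stroke female 4 the differences of list levels turned, from 0.14 to -0.05 for ribosome and from 0.11 to -0.005 for oxidative phosphorylation genes. The count was 1 without control stroke male 3, without PAE stroke female 3, or without the 3 libraries with over 40% nuclear rRNA.

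In mesenteric adipose tissue, 7 stroke and 7 naive control animals were compared to ask what stroke did in animals exposed to room air. Oxidative phosphorylation genes rose: 38 of 61 members were called higher and 54 adjusted over the list alone, with a median log2 change of 0.38 and all 61 positive (camera adjusted p = 2.12e-42, and 0.257 with an estimated correlation). The respiratory complex genes Ndufs1 and Cox6b1 rose 1.66-fold (log2 0.73 ± 0.114 SE, edgeR adjusted p = 0.000657) and 1.49-fold (log2 0.58 ± 0.0932 SE), Cox6b1 from 52.2 ± 6.73 to 76.5 ± 6.15 CPM. Cpt1b, the carnitine palmitoyltransferase that admits fatty acids to mitochondria, rose 3.93-fold (log2 1.97 ± 0.156 SE, edgeR adjusted p = 3.72e-08), from 9.36 ± 1.18 to 35.8 ± 7.80 CPM. Of 29 fatty acid oxidation genes 4 rose (Cpt1b, Hadhb, Cpt2 and Etfdh), and 6 adjusted over the list alone (camera adjusted p = 2.3e-05, and 0.678 with an estimated correlation). Dgat2, the acyltransferase that completes triglycerides, rose 3.04-fold (log2 1.60 ± 0.289 SE, edgeR adjusted p = 0.00234), from 185 ± 83.3 to 554 ± 149 CPM. All 7 stroke libraries lay above the naive mean of their sex for Ndufs1, Cox6b1, Cpt1b and Dgat2.

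Of 21 fatty acid synthesis genes 3 rose (Dgat2, Mlxipl and Gpam) in control fat, and adjusted over the list alone 10 were higher and 1 lower (median log2 change 0.85; camera adjusted p = 8.17e-07, and 0.678 with an estimated correlation). Cholesterol synthesis genes rose in 8 of 24 members and in 13 adjusted over the list alone (median 0.51; camera adjusted p = 1.92e-10, and 0.257 with an estimated correlation), among them Mvk (1.46-fold) and Nsdhl (1.57-fold). Gulo, which encodes the last enzyme of vitamin C synthesis, was 15.4-fold lower (log2 -3.95 ± 0.524 SE, edgeR adjusted p = 0.000129), at 2.20 ± 3.09 CPM against 22.5 ± 12.4. Gprin3 was 7.84-fold lower (log2 -2.97 ± 0.563 SE, edgeR adjusted p = 0.00353), and the melanocortin receptor gene Mc5r was 7.67-fold higher (log2 2.94 ± 0.612 SE, edgeR adjusted p = 0.0073). Trem3 rose 5.04-fold and Pigz rose 4.57-fold. All 7 stroke libraries lay on 1 side of the naive mean for these 5 genes. Lep, the leptin gene, did not pass (log2 1.63 ± 0.478 SE, edgeR adjusted p = 0.0513). The log2 changes of Adipoq (-0.19), Plin1 (0.11), Pparg (0.22), Ccl2 (0.87), Cd68 (0.16), Fkbp5 (0.86), Pdk4 (-0.36) and Angptl4 (-0.45) did not pass either, and Ucp1 had too few counts to be tested.

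The 8 other lists that passed camera in control fat had few or no called members. Heat shock genes rose in 2 of 14 members over all genes and adjusted over the list alone, the mitochondrial chaperone genes Hspe1 and Hspd1 by log2 0.58 and 0.61 (camera adjusted p = 0.0388, and 0.678 with an estimated correlation). Ccne1 was the 1 called member of 30 cell cycle genes, over all genes and adjusted over the list alone (list median 0.89; camera adjusted p = 2.19e-05, and 0.678 with an estimated correlation). Orm1, at less than 1 CPM, was the 1 called member of 19 acute phase genes, with 2 adjusted over the list alone (camera adjusted p = 0.0377, and 0.678 with an estimated correlation). MHC class II genes had a median of -1.67, with 6 of 10 lower adjusted over the list alone but none over all genes (camera adjusted p = 0.00504, and 0.678 with an estimated correlation). T and NK cell markers, smooth muscle markers, interferon response genes and ribosomal protein genes had medians of -1.11, -1.28, -0.37 and 0.16, with no called member. Their camera adjusted p were 0.00358, 0.0171, 0.00486 and 8.59e-07, and each had an adjusted p = 0.678 with an estimated correlation. MHC class II genes stood at 6.49 log2 CPM in control naive male 3, against 2.37 to 3.17 in the other naive libraries, and T and NK markers at 1.84, against -0.37 to 0.42. Without it the changes of list levels went from -0.85 to -0.23 and from -0.73 to -0.42, and that of interferon genes from -0.31 to -0.12. The smooth muscle level changed by 0.10 in females and -1.70 in males. The adipocyte markers did not pass (median 0.20, camera adjusted p = 0.0747).

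In adipose tissue of control animals edgeR called 783 of 18546 genes (604 higher and 179 lower), 99 of them over 2-fold. Of 30 named genes called, 16 were called whichever single library was left out, including Cpt1b, Dgat2 and Gulo. The count was 487 and 494 without control naive females 1 and 3, 462 without control naive male 2 and 403 without control stroke male 3. With the sexes pooled it was 431, which ended the calls of Mlxipl, Gpam, Hadhb, Cpt2, Etfdh, Hspe1 and Hspd1, and by DESeq2 it was 1332.

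The adipose comparison of 8 stroke with 8 naive PAE animals asked the same after prenatal ethanol. Ribosomal protein genes rose in 30 of 51 members and in 46 adjusted over the list alone, with a median log2 change of 0.31 (camera adjusted p = 2.74e-28, and 0.438 with an estimated correlation). Rps27a rose 1.49-fold (log2 0.57 ± 0.112 SE, edgeR adjusted p = 0.00523), from 136 ± 23.8 to 202 ± 13.4 CPM, and Rplp0 1.44-fold. Adipoq, which encodes the adipocyte hormone adiponectin, fell 1.73-fold (log2 -0.79 ± 0.162 SE, edgeR adjusted p = 0.00723), from 3559 ± 741 to 2093 ± 585 CPM. Lpl, the lipoprotein lipase gene, fell 1.74-fold (log2 -0.80 ± 0.169 SE, edgeR adjusted p = 0.00847), from 5322 ± 1262 to 3067 ± 641 CPM. Lcn2 rose 10.4-fold (log2 3.38 ± 0.586 SE, edgeR adjusted p = 0.00228), from 5.67 ± 1.70 to 94.7 ± 145 CPM. All 8 stroke libraries moved in the stated direction from the naive mean of their sex for these 5 genes. Fkbp5 rose 2.64-fold (log2 1.40 ± 0.312 SE, edgeR adjusted p = 0.0112), and 7 of 8 stroke libraries were higher.

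Lipolysis and lipid droplet genes fell in 3 of 20 members (Lpl, Adrb1 and Pnpla2), and adjusted over the list alone 9 were lower and 1 higher (median log2 change -0.32; camera adjusted p = 0.000161, and 0.571 with an estimated correlation). Of 15 adipocyte markers 3 fell (Adipoq, Pnpla2 and Cfd), and adjusted over the list alone 8 were lower and 1 higher (median -0.36; camera adjusted p = 0.00121, and 0.571 with an estimated correlation), while their mean level changed by 0.08 in females and -0.48 in males. Acute phase genes rose in 4 of 19 members (Lcn2, Lbp, Cp and Fgg) and in 6 adjusted over the list alone (median 0.48; camera adjusted p = 0.00196, and 0.438 with an estimated correlation). Lbp, which encodes lipopolysaccharide-binding protein, rose 2.00-fold. Cell cycle genes rose in 3 of 30 members (Mcm2, Mcm3 and Ccne2) and in 27 adjusted over the list alone (median 1.37; camera adjusted p = 6.32e-10, and 0.571 with an estimated correlation). Cholesterol synthesis genes rose in 2 of 24 members (Mvk and Acat2) and in 5 adjusted over the list alone (camera adjusted p = 0.00485, and 0.745 with an estimated correlation). Oxidative phosphorylation genes rose in 4 of 61 members and in 9 adjusted over the list alone (median 0.11; camera adjusted p = 0.00485, and 0.784 with an estimated correlation). The list level changed by 0.41 in females and -0.21 in males. The 4 called genes rose in the mean of the sexes, but the male log2 changes of Sdhd and Cox5a were -0.07 and -0.02, against 0.65 for each in females.

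Marker lists of other cell types passed camera in the same PAE fat, none of them with an estimated correlation. Smooth muscle markers fell in 2 of 8 members (Actg2 by log2 -2.61 and Cnn1 by -2.33) and in 5 adjusted over the list alone (median -1.29; camera adjusted p = 0.00485, and 0.745 with an estimated correlation). The 7 neuronal markers had a median of -1.84, with 1 lower adjusted over the list alone (camera adjusted p = 0.00485, and 0.571 with an estimated correlation). All 14 macrophage markers were higher on average, with a median of 0.61 and no called member (camera adjusted p = 0.0086, and 0.745 with an estimated correlation). The 13 B and plasma cell markers had a median of 2.07, with 8 higher adjusted over the list alone (camera adjusted p = 0.0297, and 0.776 with an estimated correlation), and their level changed by -0.06 in females and 1.46 in males. In PAE stroke male 2 their mean was 5.71 log2 CPM, against -0.66 to 0.31 in the other 3 males of its group, and without this library the list had the opposite direction and a camera adjusted p of 0.746. The 28S rRNA gene Rn28s was 5.70-fold lower after stroke (log2 -2.51 ± 0.626 SE, edgeR adjusted p = 0.0198).

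Gulo fell in PAE fat too, 13.6-fold (log2 -3.76 ± 0.457 SE, edgeR adjusted p = 6.54e-05), and Tnr fell 9.51-fold, while Mc5r rose 7.93-fold (log2 2.99 ± 0.582 SE), each in all 8 stroke libraries. The log2 changes of Lep (-0.24), Plin1 (-0.36), Pparg (-0.05), Ccl2 (0.13), Cd68 (0.76), Pdk4 (-0.09) and Angptl4 (-0.53) did not pass. In PAE animals edgeR called 1165 of 18546 adipose genes (614 higher and 551 lower), 254 of them over 2-fold. Which direction held more genes was not stable: lower genes outnumbered higher ones with RLE scaling, with the compared libraries alone, by DESeq2 and without libraries with over 40% nuclear rRNA. Of 33 named genes called, 15 were called whichever single library was left out, including Adipoq, Lpl and Lcn2. The count was 702 without PAE naive female 1, 723 without PAE naive male 4, and 744 and 647 without PAE stroke females 2 and 3. It was 611 with the nuclear rRNA share as a covariate, which ended the calls of Rn28s (itself part of that share), Adrb1, Pnpla2, Fgg, Mcm2, Mcm3 and Ccne2. It was 611 with the compared libraries alone, which also ended those of Actg2, Cp, Acat2, Sdhd and Cox5a, and 741 without a filter on low counts. The control and PAE calls shared 196 higher genes where 20.0 would be shared by chance, and 98 lower genes where 5.32 would be.

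**Figure D3:**
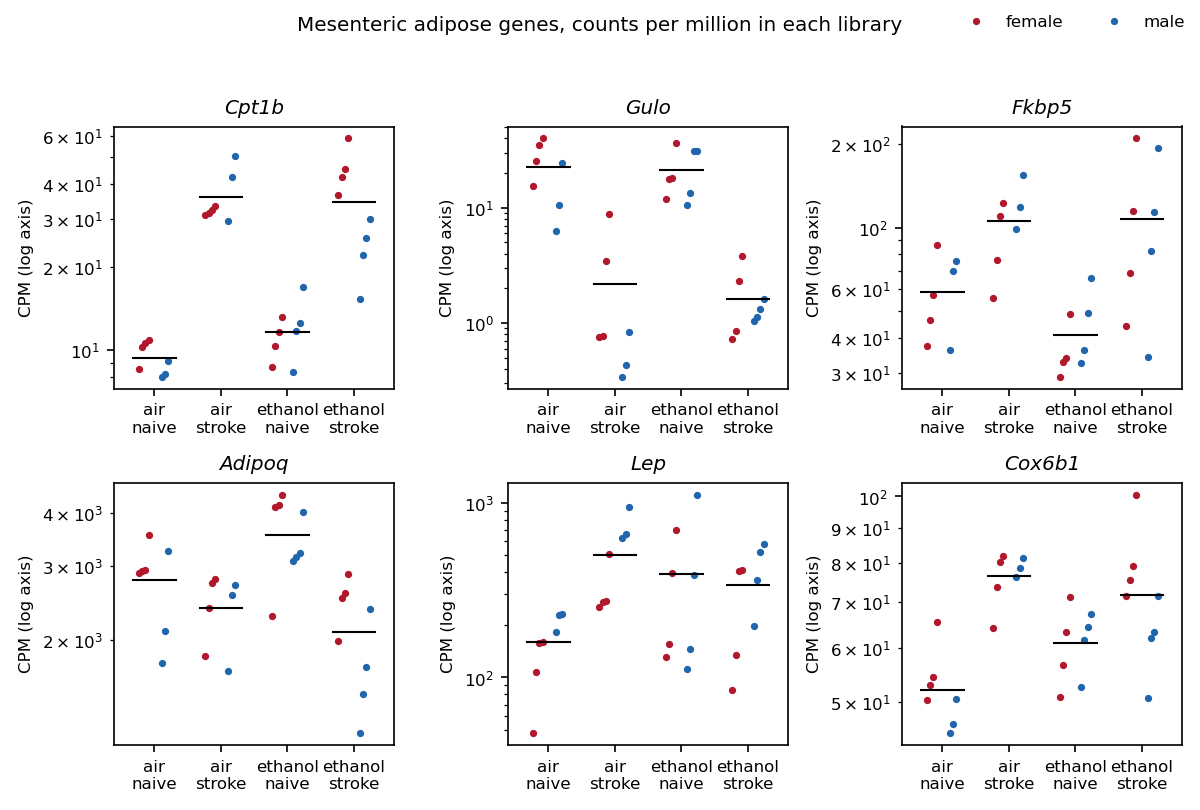
CPM (y axis, log scale) of Cpt1b, Gulo, Fkbp5, Adipoq, Lep and Cox6b1 in each mesenteric adipose library by exposure and stroke group (x axis), with red points for females, blue points for males and a line at the group mean. Adipoq averaged 2093 CPM in PAE stroke and 3559 CPM in PAE naive libraries.

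The exposure by stroke interaction in adipose tissue asked whether fat responded to stroke differently after prenatal ethanol. No gene passed in edgeR, 1125 had an unadjusted p under 0.05 where 927 would by chance, and DESeq2 called 1. The stroke response of Lep differed by log2 -1.87 ± 0.64 SE, that of Adipoq by -0.60 ± 0.238 and that of Plin1 by -0.47, at an edgeR adjusted p of 0.791 for all 3. LOC103694176 (-1.07 ± 0.187, adjusted p = 0.106) had the smallest p, followed by Rnd1 (-1.23 ± 0.283), the synaptic gene Unc13a (-0.63 ± 0.146), Esrrb (-1.42 ± 0.34) and LOC681410 (0.49 ± 0.118) at 0.791. Oxidative phosphorylation genes had a negative difference in 60 of 61 members, with a median of -0.30 (camera adjusted p = 3.29e-33, and 0.275 with an estimated correlation). Their mean level was 5.57 ± 0.202 log2 CPM (SD, n = 7) in control naive, 5.95 ± 0.0818 (n = 7) in control stroke, 5.78 ± 0.144 (n = 8) in PAE naive and 5.88 ± 0.354 (n = 8) in PAE stroke libraries. By sex, the difference of the list levels was 0.14 in females and -0.74 in males, so the direction was that of the males. All 15 adipocyte markers had a negative difference, with a median of -0.47 and 1 lower adjusted over the list alone (camera adjusted p = 1.87e-10, and 0.275 with an estimated correlation). Their levels in the same 4 groups were 9.10 ± 0.272, 9.40 ± 0.183, 9.33 ± 0.223 and 9.13 ± 0.385 log2 CPM, and the difference was -0.005 in females and -1.08 in males. Leaving out control stroke female 1 gave 1 called gene.

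**Figure D4:**
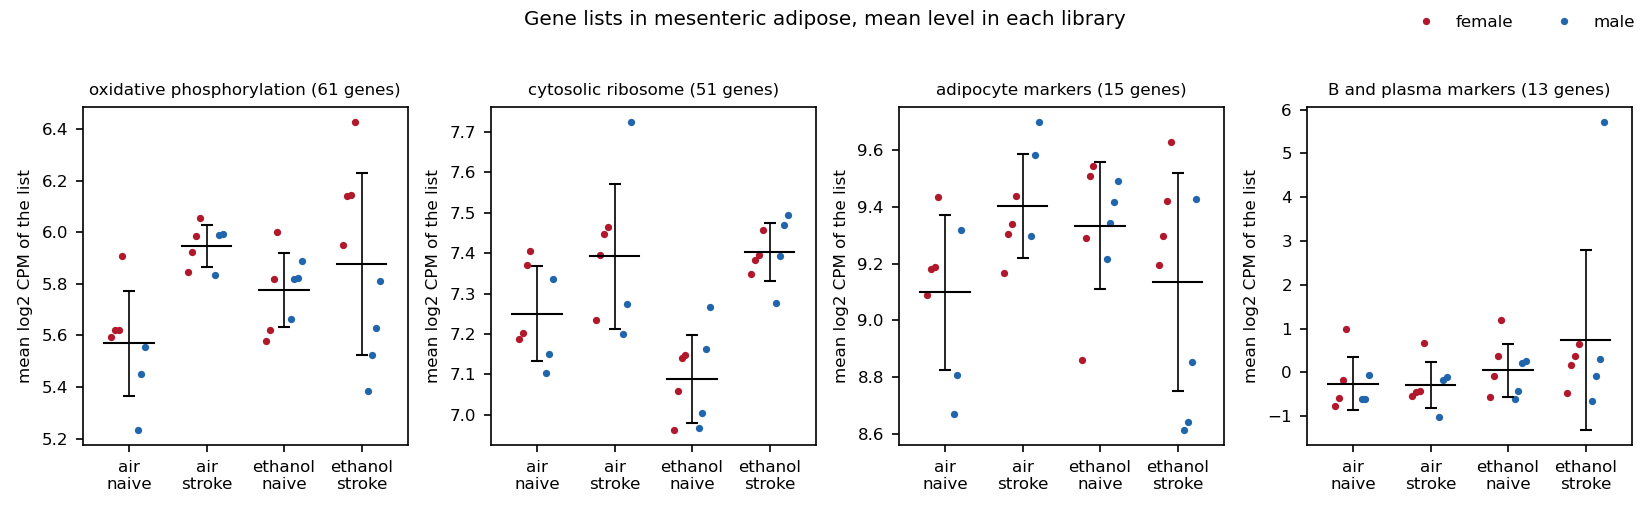
Mean log2 CPM of marker and pathway lists (y axis) in each mesenteric adipose library by exposure and stroke group (x axis), with red points for females, blue points for males, a line at the group mean and bars of 1 SD. Oxidative phosphorylation genes averaged 5.57 in control naive and 5.95 in control stroke libraries.

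Further lists passed camera in the adipose interaction, none with an estimated correlation. Ribosomal protein genes had a positive difference in 48 of 51 members (median 0.14; camera adjusted p = 4.92e-09, and 0.528 with an estimated correlation). Fatty acid oxidation, lipolysis and lipid droplet, cholesterol synthesis and fatty acid synthesis genes had medians of -0.24, -0.32, -0.20 and -0.36, at adjusted p = 0.4, 0.275, 0.527 and 0.528 with an estimated correlation. Of 35 interferon response genes 33 had a positive difference (median 0.45; camera adjusted p = 8.7e-05, and 0.666 with an estimated correlation). MHC class II genes, T and NK cell markers and B and plasma cell markers had medians of 1.54, 1.49 and 2.08, at adjusted p = 0.528, 0.528 and 0.652 with an estimated correlation. Without PAE stroke male 2 these medians were 0.89, 0.57 and -0.24, and without control naive male 3 the difference of MHC class II levels went from 0.74 to 0.12. In females and in males the differences of list levels had opposite signs for fatty acid oxidation (0.26 and -0.70), lipolysis (0.11 and -0.78), interferon (-0.29 and 0.98), MHC class II (-0.71 and 2.19), T and NK (-0.09 and 1.94) and B and plasma (-0.02 and 1.46). Ethanol and xenobiotic metabolism (median -0.34), cholangiocyte markers (0.69) and mesothelium markers (0.33) passed too, at adjusted p = 0.527, 0.474 and 0.714 with an estimated correlation. The 18 antioxidant genes passed with a median of -0.26 and a mean of 0.06, which differ in sign (camera adjusted p = 0.0138, and 0.527 with an estimated correlation).

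The adipose comparison of 8 PAE with 7 control naive animals asked what ethanol before birth left in adult fat. No gene passed in edgeR, 1257 had an unadjusted p under 0.05 where 927 would by chance, and DESeq2 called 23. Oxidative phosphorylation genes were higher on average in 60 of 61 members, with a median log2 difference of 0.25 and 32 higher adjusted over the list alone (camera adjusted p = 3.8e-36, and 0.276 with an estimated correlation). The malate dehydrogenase gene Mdh2 (log2 0.41 ± 0.0875 SE, 75.2 ± 7.07 CPM in PAE against 57.5 ± 7.90) and the mitochondrial translation gene Gfm1 (0.31 ± 0.0685) were among the 5 genes with the smallest p. The others were Unc13a (0.51 ± 0.105), Acp5 (0.94 ± 0.211) and LOC103694176 (0.71 ± 0.135). Their edgeR adjusted p was 0.321 for LOC103694176 and 0.498 for the other 4, and all 8 PAE libraries, 7 for Acp5, lay above the control mean of their sex. Lep had a log2 difference of 1.29 ± 0.461 SE, at 392 ± 353 CPM against 159 ± 65.2, and Adipoq one of 0.40 ± 0.169 (edgeR adjusted p = 0.703 and 0.711). Fkbp5 (-0.53), Cd68 (-0.56), Plin1 (0.24), Pparg (0.18), Ccl2 (0.05), Pdk4 (0.04) and Angptl4 (0.19) did not pass either. The authors' deposited table called 19 genes here (17 higher and 2 lower), among them Mdh2 (0.39), Tecr (0.42) and Ndufs3 (0.32), chosen after their values were seen.

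Fatty acid oxidation genes were higher on average in PAE naive fat in 26 of 29 members, 4 of them adjusted over the list alone (median 0.25; camera adjusted p = 2.06e-10, and 0.276 with an estimated correlation). Adipocyte markers were higher in 14 of 15 members (median 0.24, 1 adjusted over the list alone; camera adjusted p = 5.06e-06, and 0.276 with an estimated correlation). Lipolysis and lipid droplet genes were higher in 17 of 20 members, 1 of them adjusted over the list alone, fatty acid synthesis genes in 18 of 21 and cholesterol synthesis genes in 21 of 24. Their medians were 0.22, 0.34 and 0.15, at adjusted p = 0.276, 0.374 and 0.374 with an estimated correlation. Ribosomal protein genes were lower in 48 of 51 members, 1 of them adjusted over the list alone (median -0.16; camera adjusted p = 9.37e-18, and 0.276 with an estimated correlation). All 7 neuronal markers were higher (median 1.26), and all 10 mesothelium and all 6 cholangiocyte markers lower (medians -0.26 and -0.36), at adjusted p = 0.276, 0.597 and 0.276 with an estimated correlation. Interferon response (median -0.16), ethanol and xenobiotic metabolism (0.30) and negative acute phase genes (0.37, 1 adjusted over the list alone) also passed camera, at adjusted p = 0.827, 0.276 and 0.235 with an estimated correlation, the interferon level differing by 0.03 in females and -0.43 in males.

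In stroke animals, the fat of 8 PAE and 7 control animals was compared to ask whether the exposures differed after stroke. No gene passed in edgeR, 703 had an unadjusted p under 0.05 where 927 would by chance, and DESeq2 called 1. The smallest p belonged to LOC681410 (log2 0.34 ± 0.0834 SE), the clock gene Clock (-0.27 ± 0.0682), Rnd1 (-0.76 ± 0.198), Lfng (-0.49 ± 0.128) and Fcgbp (2.05 ± 0.542), all at an edgeR adjusted p of 1. Adipoq (-0.21 ± 0.168), Lep (-0.58), Plin1 (-0.23), Pparg (-0.10), Ccl2 (-0.69), Cd68 (0.03), Fkbp5 (0.01), Pdk4 (0.31) and Angptl4 (0.11) did not pass. All 13 B and plasma cell markers were higher on average, with a median of 2.60 and 12 higher adjusted over the list alone (camera adjusted p = 8.95e-10, and 0.566 with an estimated correlation). All 10 MHC class II genes were higher, with a median of 1.19 and 4 adjusted over the list alone (camera adjusted p = 2.52e-06, and 0.66 with an estimated correlation), and T and NK markers had a median of 1.31 (camera adjusted p = 0.000151, and 0.869 with an estimated correlation). Without PAE stroke male 2 these medians were 0.23, 0.58 and 0.34. All 15 adipocyte markers were lower, with a median of -0.20 (camera adjusted p = 4.29e-06, and 0.566 with an estimated correlation). The 6 gut epithelium markers were all higher (median 1.13, 3 adjusted over the list alone) and the pancreas acinar markers had a median of 0.53 (1 adjusted over the list alone), at adjusted p = 0.228 and 0.66 with an estimated correlation. Oxidative phosphorylation, heat shock, lipolysis and lipid droplet, immediate early and interferon response genes passed camera with medians of -0.07, -0.08, -0.10, -0.20 and 0.22, at adjusted p = 0.969, 0.869, 0.869, 0.969 and 0.969 with an estimated correlation. List levels differed in opposite directions in females and in males for adipocyte markers (0.07 and -0.64), oxidative phosphorylation (0.21 and -0.35), lipolysis (0.28 and -0.48), interferon (-0.26 and 0.55) and pancreas acinar markers (1.25 and -0.26). The acinar difference went from 0.50 to 0.26 without PAE stroke female 2, and the interferon difference turned from 0.14 to -0.05 without PAE stroke male 4. Without PAE stroke male 2 only 5 of the 11 lists passed camera.

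Genes called after stroke in both tissues were counted over 14895 genes tested in each, and the labels do not say whether a number stands for the same animal in both tissues. In controls 28 genes were called higher in both where 10.4 would be by chance, and 1 lower where 1.39 would be. In PAE animals 64 were called higher in both where 26.0 would be by chance, and 21 lower where 8.84 would be.

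Males and females were compared to check the sex labels and to size the sex difference. The Y-linked genes Kdm5d and Eif2s3y averaged 50.3 ± 3.61 and 49.4 ± 7.96 CPM (SD) in the 14 male adipose libraries and 0 in the 16 female ones. In liver, Kdm5d and Eif2s3y averaged 26.2 ± 3.07 and 14.0 ± 3.07 CPM in males, and 0.0041 and 0 in females. The male-specific liver cytochrome gene Cyp2c11 averaged 1055 ± 376 CPM in males and 0.234 ± 0.205 in females, where counts were near the floor of 3 per library. Cyp2c12, the female-specific one, averaged 93.0 ± 72.0 CPM in males and 2944 ± 883 in females (log2 -5.01 ± 0.284 SE, edgeR adjusted p = 1.5e-13). Ddx3y did not reach the count needed for a test.

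The liver differed between the sexes in 5166 of 15889 genes (2550 higher in males and 2616 lower), and in 3109 with the nuclear rRNA share as a covariate. Adipose tissue differed in 1525 of 18546 genes (840 higher in males and 685 lower), and in 98 with that covariate. The adipose count was 630 without control naive male 3, 1013 and 938 without PAE naive females 2 and 3, 1005 without PAE naive male 1 and 523 without control stroke male 2. It was 931 and 963 without PAE stroke females 2 and 4, and 890 and 2391 without PAE stroke males 1 and 3. It was 936 with the number in the labels as a block and 2472 by DESeq2. The adipose stroke response did not differ between the sexes for any gene in edgeR, with 1018 genes at an unadjusted p under 0.05 and 14 called by DESeq2. The difference between the sexes in the response to PAE gave 0 called genes in edgeR in both tissues, with 994 adipose and 321 liver genes at an unadjusted p under 0.05 and 0 called by DESeq2, and leaving out control naive male 2 gave 1 in liver.

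In liver 20 genes differed between the sexes in their stroke response in edgeR, 9 with a higher and 11 with a lower change in males. Cux2, which encodes a transcription factor more abundant in female liver, rose in males by log2 3.16 ± 0.436 SE (edgeR adjusted p = 6.96e-05), from 4.36 ± 3.84 to 45.1 ± 28.1 CPM in 7 animals each, and stood at 220 ± 48.7 and 205 ± 36.2 CPM in stroke and naive females (n = 8 each). The sexes differed by 3.06 ± 0.551 (edgeR adjusted p = 0.0261). Plaat3 rose by 1.84 ± 0.209 in males and differed by 1.43 ± 0.267. Akr7a3, an aldehyde reductase gene, fell in males by log2 -1.75 ± 0.223, from 89.7 ± 31.3 to 28.2 ± 10.8 CPM, and differed by -1.73 ± 0.297. Cryl1 and Ajuba fell in males by -2.00 ± 0.242 and -1.24 ± 0.153. The epoxide hydrolase gene Ephx1 fell by -0.96 ± 0.185, and Ca8 and Enc1 by -0.59 and -1.05. Ldhd rose in females by 0.60 (edgeR adjusted p = 0.00253) and had a log2 change of -0.38 in males (0.0812).

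None of the 10 liver genes with the smallest p for the sex difference in stroke response passed in every fit that left out a single library. The count was 12, 8 and 0 without control naive females 1, 3 and 4, and 9, 9 and 0 without control naive males 1, 2 and 3. It was 10 and 10 without PAE naive females 1 and 3, and 8, 9 and 3 without PAE naive males 2, 3 and 4. It was 7 and 8 without control stroke females 2 and 3, 9 without control stroke male 1, 10 and 10 without PAE stroke females 1 and 2, and 10, 3 and 7 without PAE stroke males 2, 3 and 4. It was 0 without the 3 libraries with over 40% nuclear rRNA, 9 with the rRNA share as a covariate and 88 by DESeq2.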

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

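The tests of the length bias and of the rRNA share on the oxidative phosphorylation pattern, the rRNA covariate and the fits without PAE stroke male 2 or with an adipocyte covariate were chosen only after the results were seen.

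Within groups of 4 libraries, 14 of 270 checks found a library far from the other 3 by Dixon's criterion, and chance alone picks about 1 in 20 groups. In total counts, liver control naive female 2 had 7.72 M against 17.3 M to 17.8 M, and liver PAE stroke male 2 had 8.11 M against 23.4 M to 26.4 M. Nuclear rRNA took 42.4% of the counts of liver PAE stroke male 2 against 1.09% to 2.14%, and mitochondrial rRNA took 31.5% in adipose control stroke female 3 against 19.1% to 20.6%. Haemoglobin genes took 0.142% in liver control stroke female 2 against 0.0249% to 0.0398%. In mean log2 CPM, B and plasma cell markers stood at 0.68 in adipose control stroke female 3 (others -0.53 to -0.41), at 5.71 in adipose PAE stroke male 2 (others -0.66 to 0.31) and at -0.82 in liver PAE naive male 2 (others -0.04 to 0.12). Fibroblast markers stood at 7.82 in adipose PAE stroke female 1 (others 6.29 to 6.49) and neuronal markers at 1.56 in adipose control stroke female 1 (others -0.60 to -0.33). In liver, neutrophil markers stood at -0.996 in PAE stroke female 3 (others 0.19 to 0.35). T and NK markers stood at 0.22 in control naive female 1 (others 0.66 to 0.68) and at -1.21 in PAE stroke male 2 (others -0.40 to -0.26). Cholangiocyte markers stood at 0.32 in PAE stroke female 4 (others 0.73 to 0.80).

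The stroke response of 20 liver genes differed between the sexes by the interaction test. The log2 differences, male response minus female response, were -1.73 for Akr7a3, -0.99 for Ldhd, -1.78 for Cryl1, -1.35 for Ephx1, 1.43 for Plaat3, 3.06 for Cux2, -1.08 for Ajuba, -1.002 for Ca8, -1.48 for Enc1 and -6.04 for Cyp2c24, whose female counts were at the floor so that its size is not a measured fold. Of 100 splits of the liver libraries 2 called as many genes, the real one included. The real split called 20 and the highest other 63. Their share lay under the 0.05 set beforehand, but regrouping also breaks up the stroke response the sexes share, so chance is not excluded. Single libraries ended all 20 calls.

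Lymphocyte marker lists passed camera at the preset correlation as higher in the adipose tissue of PAE stroke than of control stroke animals, but none did with an estimated correlation (adjusted p = 0.566 for B and plasma, 0.869 for T and NK and 0.66 for MHC class II). A candidate explanation is lymph node tissue in 1 library, PAE stroke male 2, since mesenteric fat holds lymph nodes. Without it the median log2 difference of B and plasma markers went from 2.60 to 0.23 and the camera adjusted p to 0.0625, and that of T and NK markers from 1.31 to 0.34 with an adjusted p of 0.284, as this explanation needs. The median of MHC class II genes went from 1.19 to 0.58 with an adjusted p of 0.00208, which argues against that library as the whole cause for this list, at the preset correlation only. A change in resident immune cells with exposure stays open and was not tested apart from it.

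Oxidative phosphorylation genes had a lower stroke response in PAE than in control adipose tissue (median log2 difference -0.30) in the mean of the sexes. The list level differed by 0.14 in females and -0.74 in males, so the pattern was that of the males, and whether the sexes differ in it was not tested. Ribosomal protein genes, also short, had a median of 0.14, the opposite sign, but did not pass with an estimated correlation. A bias against short transcripts thus stays open. The nuclear rRNA share is argued against by a median of -0.26 that remained with it as a covariate. With the adipocyte marker level as a covariate the median was -0.017. A difference in the adipocyte share may thus carry the pattern, as may a change within adipocytes that moves markers and mitochondrial genes together. Exchanging the exposure labels within stroke and sex groups gave a difference of list levels as large as -0.30 with a two-sided permutation p = 0.0519, so chance could not be excluded. Prenatal exposure itself stays open.

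In adipose tissue 1525 genes were called between the sexes but 98 with the nuclear rRNA share as a covariate, and that share was far lower in PAE stroke males than in females. If the rRNA difference in PAE animals were the whole cause, genes called between the sexes of PAE animals should not keep their sign in controls, yet 94.1% of 152 did. The covariate left a median of 0.866 of the log2 fold change of the called genes (quartiles 0.755 to 1.001) and raised their SE 1.23-fold, so the calls ended by smaller changes and larger errors together, and the covariate itself was called for 5 genes. These values argue against the rRNA share as the carrier of the fold changes, while a partial share of 1 minus that ratio stays open beside the sex of the animals, which the design names.

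Splits of the same libraries into groups of the same sizes, 100 per comparison with the real one included, were used to ask whether chance can be excluded. In 1 of 100 splits, the real one, the count was as large for adipose stroke in controls (783, highest other 1) and in PAE animals (1165, highest other 1), adipose sex (1525, highest other 0), liver stroke in controls (468, highest other 427) and in PAE animals (1112, highest other 2), and liver sex (5166, highest other 1), so chance was excluded for these. For the other comparisons the real count was 0, which all 100 splits reach whatever they call, so the splits decide nothing about them. Their highest other counts were 246 for adipose PAE against control in naive and 392 in stroke animals, 3 for the adipose interaction, 0 for adipose sex by stroke and 3 for adipose sex by PAE. In liver they were 4 for PAE against control in naive and 788 in stroke animals, 1 for the interaction and 4 for sex by PAE. The splits with 246, 392 and 788 calls point to a structure of the samples other than the tested groups, which was not examined.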

How the results depend on the processing

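The rRNA covariate, the removal of rRNA genes, the fits without high-rRNA libraries, without adipose PAE stroke male 2 and with an adipocyte covariate were alternatives chosen after seeing the data. Counts of called genes stayed within 1.5 times the reported one with RLE scaling and with rRNA genes removed. By DESeq2 they were 23 for adipose PAE naive, 1332 for stroke control, 1 for PAE stroke, 1 for the interaction, 2472 for sex and 14 for sex by stroke, and in liver 736 for stroke control, 12 for PAE stroke and 88 for sex by stroke. With no sex term, adipose stroke control gave 431, liver stroke control 222 and liver stroke PAE 579. Adipose stroke PAE gave 741 without the low-count filter, 611 with the compared libraries alone, 611 with the nuclear rRNA covariate and 702 with libraries over 40% nuclear rRNA left out. The rRNA covariate gave 98 for adipose sex, 3109 for liver sex and 9 for liver sex by stroke, and leaving out libraries over 40% gave 1 for liver PAE stroke, 1 for the liver interaction and 0 for liver sex by stroke. The labels do not say that sample numbers pair animals, and same-number libraries had a median correlation of 0.0746 in adipose tissue (20 of 43 over 0.1) and 0.103 in liver (23 of 43), against -0.0207 and -0.0451 for different numbers, and in liver 7 of 8 same-number pairs of PAE naive and stroke animals exceeded 0.1, all 4 of the males among them. With the number as a block, adipose stroke control gave 666 genes (532 higher, 134 lower), stroke PAE 883 (436 higher, 447 lower) and sex 936 (443 higher, 493 lower). In adipose stroke PAE lower genes outnumbered higher ones with this block, with RLE scaling (534 higher, 594 lower), with the compared libraries alone (277, 334), by DESeq2 (853, 885) and without libraries over 40% nuclear rRNA (309, 393). The block ended the calls of Rn28s, Actg2, Fgg, Pnpla2, Mcm2, Mcm3 and Ccne2 in adipose stroke PAE, of Gpam and Etfdh in adipose stroke control of Chac1 and Sdf2l1 in liver stroke control and of Ca8, Enc1 and Cyp2c24 in liver sex by stroke, where 14 genes were called. Leaving out the library that moved a list most lowered the level difference over 1.5 times for 1 of 13 lists in adipose PAE naive, 8 of 12 in stroke control, 3 of 11 in stroke PAE, 9 of 11 in PAE stroke and 7 of 15 in the interaction, and in liver for 5 of 8, 1 of 18, 3 of 17, 4 of 11 and 4 of 7. Leaving out each library in turn gave 403 to 983 for adipose stroke control, 647 to 1566 for stroke PAE, 0 to 1 for the interaction and 523 to 2391 for sex. In liver it gave 279 to 456 for stroke control, 789 to 1260 for stroke PAE, 0 to 1 for PAE stroke, 4500 to 5736 for sex, 0 to 30 for sex by stroke and 0 to 1 for sex by PAE; the other comparisons stayed at 0 to 0. Without adipose PAE stroke male 2 the B and plasma markers reversed, at camera adjusted p of 0.746 in stroke PAE and 0.597 in the interaction. With the adipocyte covariate 6 of 13 lists still passed in the same direction in adipose PAE naive, 6 of 12 in stroke control, 8 of 11 in stroke PAE, 6 of 11 in PAE stroke and 2 of 15 in the interaction. The direction reversed for interferon genes in PAE naive (0.522), stroke control (0.765), PAE stroke (0.0144) and the interaction (0.0415). It reversed in PAE stroke for lipolysis (0.0381), oxidative phosphorylation (9.58e-07) and adipocyte markers (0.174), and in the interaction for fatty acid synthesis (0.05004), lipolysis (0.688), ethanol and xenobiotic metabolism (0.688), antioxidant genes (0.862) and adipocyte markers (0.688); the covariate is made of adipocyte markers, so its values for that list decide nothing. The cause was not tested for these changes, except that fewer libraries enter the fits that leave some out. Depth limits the libraries with high rRNA, where as few as 4.19 M counts in liver and 4.74 M in adipose tissue lay outside rRNA.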

Other observations

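The test of the sex-biased gene score was planned after the genes with a sex difference in stroke response were seen, and before the score was computed; the test of pairs was chosen only after the scores were seen.

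Inflammatory cytokine and adhesion genes did not pass as a list after stroke in either tissue. The liver list of 14 measured members gave camera adjusted p of 0.911 in control and 0.253 in PAE animals, and the adipose list of 20 members gave 0.0919 and 0.413.

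The genes with a sex difference in liver stroke response raised the hypothesis that stroke may narrow the liver's sex difference in males. A score was made from 675 other genes that differed at least 2-fold between the sexes of naive controls, the mean log2 CPM of 301 female-higher genes minus that of 374 male-higher genes. In PAE animals, which did not define the genes, the score was -1.15 ± 0.191 (SD, n = 4) in stroke males and -1.99 ± 0.203 (n = 4) in naive males, a difference of 0.83 (exact two-sided permutation p = 0.0286, the smallest that 70 splits can give). Same-number PAE naive and stroke males deviated together in liver (correlations of 0.206 to 0.271); if the numbers pair them, the 4 differences of 0.62 to 1.08 give an exact sign-flip p of 0.125, the smallest that 4 pairs allow, so chance is not excluded then. Female-higher genes were up by 0.35 and male-higher genes differed by -0.48, each at the same exact p. PAE females differed by -0.08 (exact permutation p = 0.743), and the difference between the sexes was not tested for the score. The values are consistent with the hypothesis, but PAE males had also taken part in the test of the genes that raised it. Nuclear rRNA also differed between these males, at 10.7% to 18.8% in the 4 naive ones and 1.09% to 2.14% in 3 stroke ones, which scored -1.32, -0.91 and -1.30. PAE stroke male 2, at 42.4%, scored -1.09. The part of the rRNA share in the score was not tested.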
